A study of Mus musculus with 2 samples.

How the data were processed

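Leukocytes (CD45+ cells) were sorted from mouse brain tumours that grew from CT2A cells, a mouse glioblastoma line, after injection into the brains of C57BL/6J mice. The injected cells carried either a vector control (VC) or a knockout of Comt (KO), the gene for catechol-O-methyltransferase, an enzyme that inactivates dopamine, noradrenaline and adrenaline. Tumours were taken on day 12 (D12) or day 25 (D25). Per the labels, each of 13 samples was marked with an antibody carrying a sample tag, the tagged samples were combined into 2 pools, and each pool was captured on the BD Rhapsody platform and read as a whole transcriptome library. Pool 1 held 4 VC_D12 and 3 KO_D12 samples, and pool 2 held 3 VC_D12 and 3 KO_D25 samples. Groups and replicate numbers followed the tag lists of the labels. The labels do not say that each tag marks a separate animal, so samples may be technical replicates, and every p-value measures only the spread between these samples.

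For both pools, the deposited sample tag calls assign each cell to a tag, to a multiplet or to no tag. For pool 2, the deposited expression table gives the molecule count (unique molecular identifiers, UMIs) per gene and cell, without normalisation, after the pipeline's correction of identifier errors. Per the file headers, the authors ran the BD Rhapsody WTA Analysis Pipeline 1.11.1 with GENCODE M19 on GRCm38, counted intronic reads and called cells from their mRNA with refinement. The submitters' processing notes name the build mm10. The expression matrix of pool 1 was not analysed here. Strand use was not given in the sources used here. Coordinates are those of GENCODE M21 on GRCm38.

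The table of pool 2 held 6602 cells, 28794 genes and 199271841 UMIs, with a median of 22354.5 UMIs and 4175 genes per cell. Per sample, the totals ran from 7925599 to 11606991 UMIs in KO_D25 and from 42590992 to 60628237 in VC_D12. Removal of 222 tag multiplets left 6380 cells. A minimum of 200 genes and less than 20% mitochondrial UMIs left 6153 cells. Removal of doublets called by scrublet (in scanpy, expected rate 0.06) left 6090 cells, of which 5374 carried a sample tag. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes were scaled with values limited to 10, and 30 principal components and 15 nearest neighbours gave a shared neighbour graph. Leiden clustering at a resolution of 1.0 (seed 0) gave 23 clusters. Clusters were named from marker lists fixed before the data were examined. A marker counted as present when its cluster mean reached 0.25 of the highest cluster mean and 0.1 of the cells had a UMI. At least 3 markers were required, and the 10 genes highest over the median cluster had to hold no more markers of another type than of the named one. These numerical limits were set after the data were seen. They gave 15 named classes and 1 unnamed cluster.

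The share of each class per sample was compared with a two-sided exact permutation test, for which 3 against 3 samples allow no p below 0.1, and with the edgeR quasi-likelihood test on cells per class with the sample's tagged cells as library size. UMIs were summed per class and sample. Genes kept by filterByExpr were tested with the edgeR robust quasi-likelihood test after TMM (trimmed mean of M values) scaling, KO_D25 against VC_D12, with p adjusted by Benjamini and Hochberg within the class and a threshold of 0.05. Log2 fold changes are given with the SE of the fit. Levels are TMM-scaled CPM (counts scaled to a common library total), given as mean ± SD of 3 samples. The minimum of 20 cells per sample chosen before the data were examined was met only by CD8 T cells. A minimum of 10, chosen after the data were seen, added macrophages, microglia and CD4 T cells. The difference of the macrophage and microglia changes was tested in edgeR as an interaction with the sample as a block. The 52 lists (29 gene lists and 23 marker lists) were fixed before the data were examined, and those with at least 5 tested genes were tested with fry of limma. Its p asks whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. The p-values were adjusted over 33 tests in CD8 T cells and over 108 tests in the other classes. The camera test of limma with a correlation estimated from the data served as the stricter alternative, and camera with a preset correlation of 0.01 was also run. A count of list members is given as adjusted over all genes of the class and as adjusted over the list alone.

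Genes were named by a rule fixed before the data were examined. It took Comt, up to 4 list members past the threshold per gene list, and the 8 largest rises and 8 largest falls (3 and 3 in CD4 T cells) among genes past the threshold with a mean of at least 20 CPM and no overlap between the groups. The text gives a selection of these. Ribosomal protein genes, predicted genes, pseudogenes and receptor segments were left out. Members of a list given beyond this rule, the leading genes of clusters and the shared genes of the T cell classes were named after their values were seen. Where a group had no UMI, the fold is a bound against a floor of 3 counts over the group. With 1 to 3 UMIs, a ratio of pooled CPM is given with an exact 95% interval. Intervals and floors cover counting error only.

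The fits were tested on simulated data made from the same libraries, with about 200 genes changed 2-fold or 4-fold. The tests found 67.0% of 2-fold and 98.0% of 4-fold changes in CD8 T cells, 22.4% and 70% in macrophages, 28.9% and 87.4% in microglia, and 14.3% and 87.0% in CD4 T cells. Between 0 and 5.85% of these calls were false. For the interaction, 61% of 4-fold differences were found. Each simulated gene had the spread typical of its level, without shifts between clusters or RNA from other cells. The macrophages and microglia of the interaction were drawn independently. These rates thus hold for the simulated counts and may not hold for the real fits.

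Alternatives fixed before the data were examined were doublets kept, at least 500 genes with less than 10% mitochondrial UMIs, Leiden 0.5 and 2.0, shares within the myeloid or lymphoid lineage, a ratio of medians for cells per sample, TMM over classes for abundance, each cell thinned to 6000 UMIs, DESeq2 with its size factors, limma-voom, no filter on low counts, camera, limma on the sample differences for the interaction, and each sample left out. Added after the data were seen were equal cell numbers per sample, 1 cluster shared by both groups, and a fit without genes more than 5 times higher in another class. The versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.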

Results

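The deposited data of pool 2 hold transcriptomes of host immune cells from CT2A brain tumours, 3 samples with vector-control tumour cells on day 12 (VC_D12) and 3 samples with COMT-knockout tumour cells on day 25 (KO_D25). Genotype and day differ together in this pool, so every comparison below is of both at once. Pool 1 compared VC_D12 and KO_D12 on the same day, and only its cells per sample were compared. Depth differed between the groups of pool 2, with a median of 14733.5 to 16322 UMIs per cell in the KO_D25 samples and 25282 to 32165 in the VC_D12 samples.

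Comt was knocked out in the injected tumour cells, while the classes compared here are immune cells of the host by their markers, so their Comt level checks no label. The gene lies on chromosome 16 (GRCm38, 18406886 to 18426852). In CD8 T cells Comt reached 64.0, 63.3 and 71.4 CPM in the VC_D12 samples and 51.3, 35.1 and 33.4 CPM in the KO_D25 samples, a log2 fold change of -0.72 ± 0.25 (adjusted p = 0.0409). With 1 sample left out it ranged from -0.95 to -0.63 and passed only without KO_D25 sample 1 (adjusted p = 0.0248). Within the 1 cluster that held most KO_D25 CD8 T cells the change was 0.16 and did not pass. It did not pass in macrophages (0.65 ± 0.32, adjusted p = 0.225), where the VC_D12 samples had 107, 125 and 129 CPM and the KO_D25 samples 149, 115 and 318 CPM. With Leiden 2.0 clusters the macrophage difference passed (0.95, adjusted p = 0.000412). In that setting a cluster led by Lpl, Gpnmb and Spp1 (207 KO_D25 and 12 VC_D12 cells) was named macrophage. At Leiden 1.0 a cluster with these leading genes was named microglia, so this call rests on a different set of cells. Comt did not pass in microglia either (-0.29 ± 0.17, adjusted p = 0.719), where it was most abundant, with 392, 338 and 440 CPM in VC_D12 and 295, 315 and 345 CPM in KO_D25. In CD4 T cells the levels overlapped, with 62.9, 47.8 and 40.9 CPM against 67.2, 41.6 and 44.7 CPM (adjusted p = 0.999).

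On the same day, the knockout and control tumours of pool 1 gave numbers of tagged cells per sample that did not differ beyond the spread between samples. The KO_D12 samples gave 313.7 ± 29.6 cells (SD, n = 3) and the VC_D12 samples 269.8 ± 73.4 (SD, n = 4), a difference of 43.9 cells (two-sided exact permutation p = 0.343). The difference was 9.0 cells without VC_D12 sample 4, 66.0 without VC_D12 sample 3 and 27.8 without KO_D12 sample 1, and the ratio of medians was 1.06. In pool 2 the KO_D25 samples gave 473.3 ± 106.0 cells and the VC_D12 samples 1414.3 ± 173.1, a difference of -941 cells (exact p = 0.1, the smallest that 3 against 3 samples allow). Cells recovered also depend on how much of each sample was loaded.

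The immune infiltrate of pool 2 had a different make-up in the 2 groups. Macrophages filled the VC_D12 samples, while the KO_D25 samples were made up of microglia, the resident macrophages of the brain, and of T cells. B cells were also enriched in KO_D25, and migratory dendritic cells were depleted. Natural killer (NK) cells and the dendritic type cDC1 were lower too, but did not pass the threshold in every fit with 1 sample left out.

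Macrophages made up 73.2% ± 8.08 of the cells in VC_D12 and 4.83% ± 1.97 in KO_D25 (SD, n = 3 in each group). In the edgeR test of abundance their share fell with a log2 fold change of -3.90 ± 0.55 (adjusted p = 5.35e-09). Microglia made up 1.39% ± 0.455 in VC_D12 and 44.6% ± 13.6 in KO_D25 (5.0 ± 0.57, adjusted p = 1.55e-11). The border between these classes moved with the clustering, since at Leiden 2.0 macrophages made up 19.7% and microglia 29.7% of KO_D25 cells. There a cluster led by Lpl, Gpnmb and Spp1, with 207 KO_D25 and 12 VC_D12 cells and 4 of 13 macrophage markers, was named macrophage. Macrophage values at Leiden 2.0 thus describe a different mix of cells. The macrophage clusters at Leiden 1.0 were themselves named on 4 to 9 of 13 markers. The 1 that held most KO_D25 macrophages had 6. Several lymphocyte classes made up more of the KO_D25 samples. CD8 T cells rose from 6.50% ± 1.14 to 20.6% ± 5.30 (1.66 ± 0.50, adjusted p = 0.00253), and CD4 T cells from 2.93% ± 1.54 to 9.92% ± 2.85 (1.77 ± 0.51, adjusted p = 0.00233). All these are shares of tagged cells, and 688 microglia without a tag call were left out. With every untagged cell given to KO_D25, microglia would make up 61.9% of its pooled cells instead of 44.3%. No CD8 or CD4 T cell lacked a tag call, so their KO_D25 shares would then be lower. With TMM scaling over the classes, which assumes that most classes keep their abundance, neither CD8 T (0.19, adjusted p = 0.645) nor CD4 T cells (0.38, adjusted p = 0.403) passed. Within the lymphoid lineage CD8 T cells made up 55.3% in KO_D25 and 52.8% in VC_D12 (exact p = 0.7), and CD4 T cells 26.4% and 21.8% (exact p = 0.4). A cluster of 48 KO_D25 and 3 VC_D12 cells, named gamma-delta T by 7 of 8 markers, rose by 5.21 ± 0.78 (adjusted p = 2.30e-08). Its leading genes included Tcrg-C1 and Trdc but also Gata3, Il1rl1, Il17rb and Il2ra, genes of innate lymphoid cells of group 2, so its identity is uncertain. B cells rose by 3.80 ± 0.73 (adjusted p = 6.60e-06). NK cells fell with a log2 fold change of -1.69 ± 0.66 (adjusted p = 0.0166), from 2.29% to 0.646% of all cells and from 17.9% to 1.70% of the lymphoid lineage, and did not pass with Leiden 2.0 clusters (-0.75, adjusted p = 0.193) or without VC_D12 sample 1 or 2 or KO_D25 sample 1 or 3. Among dendritic cells, migratory cells fell from 1.35% to 0.281% (-2.17 ± 0.81, adjusted p = 0.0131) and the cross-presenting type cDC1 from 3.22% to 0.826% (-1.97 ± 0.64, adjusted p = 0.00481). The fall of cDC1 did not pass without VC_D12 sample 2 or KO_D25 sample 2. Neutrophils rose from 0.127% to 1.01% (2.81 ± 0.84, adjusted p = 0.00253) on 5 and 13 cells, but did not pass with TMM over the classes (1.41, adjusted p = 0.0989). An unnamed cluster led by Il1r2, H2-Ab1, Ifi205 and H2-Aa, closest to the dendritic type cDC2 with 4 of 8 markers, fell from 4.98% to 0.604% (-3.06 ± 0.66, adjusted p = 5.30e-05).

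Some captured cells were not leukocytes by their transcripts. Endothelial cells rose from 0.0982% to 9.49% (6.37 ± 0.72, adjusted p = 1.55e-11), with a mean of 0.305 and 0 Ptprc UMIs (the gene of CD45) per 10000 in their 2 clusters. Cells of a tumour or mesenchymal type, led by Col3a1, Rgs5, Cald1 and Acta2, fell from 2.09% to 0.631% (-1.69 ± 0.67, adjusted p = 0.0178) with 0.312 Ptprc UMIs per 10000, and with the strict cell filter by more (-4.24, adjusted p = 0.000779). Without KO_D25 sample 3 this fall did not pass (-1.32, adjusted p = 0.106). CD8 T clusters had 18.9 and 16.9. Regulatory T cells, plasmacytoid dendritic cells and mast cells, with adjusted p = 0.762, 0.202 and 0.833, did not pass. With TMM over the classes regulatory T cells (-1.63, adjusted p = 0.018) and plasmacytoid dendritic cells (-2.60, adjusted p = 0.00317) passed. In all, 13 of 16 classes passed in edgeR. The exact permutation test of each of the passing classes except cDC1 (p = 0.2) gave p = 0.1, the smallest possible, which is 0.133 after adjustment.

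CD8 T cells of KO_D25 tumours had lower transcripts of proliferation, activation and exhaustion than those of VC_D12 tumours. Genes of glycolysis and of the respiratory chain were also lower. With an estimated correlation the glycolysis and S phase lists did not pass (adjusted p = 0.0791 and 0.0687). Il7r, Klf2 and Lef1 were higher, while the list of naive and memory genes did not pass. Most VC_D12 and most KO_D25 cells lay in different CD8 T clusters.

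Of 9099 genes tested in CD8 T cells, 869 rose and 1107 fell in KO_D25. The samples of the groups did not overlap for 37.0% of the genes, against 10% by chance for samples of equal depth. The KO_D25 samples held 764010 to 1333211 UMIs and the VC_D12 samples 1461718 to 1855648. The class held 283 KO_D25 and 256 VC_D12 cells from 2 clusters. In KO_D25, 272 cells lay in a cluster that held 67 of the VC_D12 cells, while the other cluster, with Gzmb and Nkg7 among its leading genes, held 11 KO_D25 and 189 VC_D12 cells. Within the shared cluster alone 59 genes passed, 50 of them among the 1976 of the whole class. Of the genes named in the text that could be tested there, only 4 kept their call (Mki67, Ldha, Itgax and Hpgds), while 21 were weaker and 4 reversed their direction. The cells had medians of 10304.5 to 10620 UMIs in the KO_D25 samples and 12365 to 21762.5 in the VC_D12 samples, and with every cell thinned to 6000 UMIs 1021 of 6739 genes passed.

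Cell cycle genes fell most. Of the G2 and M phase list 17 of 18 genes fell, also 17 adjusted over the list alone (adjusted p = 0.000518). Of the S phase list 15 of 16 fell, also 15 adjusted over the list alone (adjusted p = 0.00295, and adjusted p = 0.0687 with an estimated correlation). The proliferation marker Mki67 fell from 309.4 ± 53.7 to 41.9 ± 6.87 CPM (log2 fold change -2.90 ± 0.19, adjusted p = 3.86e-09, chromosome 7, 135689784 to 135716361), and passed also within the shared cluster (-2.29, adjusted p = 0.0473). Top2a, the topoisomerase that untangles replicated DNA, fell from 428 ± 124 to 51.4 ± 2.15 CPM (-3.06 ± 0.20). Rrm1, a subunit of the enzyme that makes deoxynucleotides, changed by -2.37 ± 0.22, and Uhrf1, which maintains DNA methylation at replication, by -5.42 ± 0.48. Stmn1 (-4.92 ± 0.36) and Hmmr (-5.20 ± 0.57) act on microtubules, and Cenpf (-4.67 ± 0.50) at the kinetochore. Ube2c (-5.86 ± 0.52), a ubiquitin-conjugating enzyme of mitosis, and Pclaf (-5.67 ± 0.36), a factor that binds the replication clamp, overlap the genes Tnnc2 and Trip4 on the opposite strand, so their counts are uncertain. Birc5, an inhibitor of apoptosis needed in mitosis, had 2 UMIs in KO_D25 and 492 in VC_D12, a ratio of 0.00581 (95% interval 0.000702 to 0.0211).

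Receptors of activated and exhausted T cells fell. In the exhaustion list 9 of 16 genes fell and Cxcr6 rose (adjusted p = 0.000518), with 10 lower and 2 higher adjusted over the list alone. Pdcd1, the gene of the inhibitory receptor PD-1, fell from 398 ± 62.9 to 120.6 ± 19.0 CPM (-1.72 ± 0.16, adjusted p = 2.49e-07, chromosome 1, 94038305 to 94052553). Ctla4 (-1.26 ± 0.15) and Cd160 (-2.38 ± 0.27) encode further inhibitory receptors. The lymphocyte activation list fell with 9 of 14 genes, also 9 adjusted over the list alone (adjusted p = 0.00052). Tnfrsf9, the costimulatory receptor 4-1BB, fell from 427 ± 28.9 to 40.5 ± 15.4 CPM (-3.36 ± 0.20, adjusted p = 3.86e-09, chromosome 4, 150914562 to 150946102). Its locus lies over Camta1 on the opposite strand, which leaves its count uncertain. The nuclear receptor gene Nr4a3, induced by T cell receptor signals, fell from 409 ± 45.8 to 52.9 ± 15.9 CPM (-2.92 ± 0.19). The costimulatory receptor Icos changed by -1.21 ± 0.16. The regulatory T cell list fell with 5 of 9 genes and the regulatory T cell markers with 5 of 7 (adjusted p = 0.000518 for each), each also 5 adjusted over the list alone. The fallen members, among them Il2ra (-1.71 ± 0.23), Tnfrsf4 (-3.39 ± 0.48) and Tnfrsf18 (-1.10 ± 0.20), encode mostly receptors that activated CD8 T cells also carry, besides the actin-capping protein gene Capg. Within the shared cluster Pdcd1 (-0.83, adjusted p = 0.153), Tnfrsf9 (-1.28, adjusted p = 0.325) and Top2a (-1.37, adjusted p = 0.144) did not pass.

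Metabolic genes fell with them. Of the glycolysis list 11 of 14 genes fell, 12 adjusted over the list alone (adjusted p = 0.00316, and adjusted p = 0.0791 with an estimated correlation). Ldha, the subunit of lactate dehydrogenase, fell from 596 ± 61.9 to 151 ± 4.49 CPM (-1.98 ± 0.13, adjusted p = 5.28e-09), and passed also within the shared cluster (-1.10, adjusted p = 0.0269). The glycolytic enzymes Tpi1 (-2.62 ± 0.20) and Pgk1 (-2.28 ± 0.16) moved the same way. Of the oxidative phosphorylation list 11 of 19 fell, 14 adjusted over the list alone (adjusted p = 0.000969), with Uqcrq of complex III (-1.08 ± 0.16) and Cox5a of complex IV (-1.02 ± 0.16) among them. In the hypoxia list 4 of 12 genes fell and P4ha1 rose, the same numbers as adjusted over the list alone (adjusted p = 0.00742, and adjusted p = 0.178 with an estimated correlation). P4ha1 passed only without KO_D25 sample 3 when 1 sample was left out. The fallen genes were Hilpda (-3.00 ± 0.31), which protects lipid droplets from breakdown, Bhlhe40 (-1.96 ± 0.18), a transcription factor also induced by T cell activation, Bnip3 and Slc2a1. Bhlhe40 had a change of 0.37 within the shared cluster, which did not pass. The disease-associated microglia list fell with 4 of 13 genes, 5 adjusted over the list alone (adjusted p = 0.0186, and adjusted p = 0.441 with an estimated correlation). Its fallen members, Fabp5 (-1.63 ± 0.37), Itgax (-2.31 ± 0.52), Cst7 and Lgals3, are also expressed by effector T cells, and Lgals3 passed only without VC_D12 sample 3 when 1 sample was left out. In VC_D12 CD8 T cells 50 abundant macrophage genes had a median of 1.94% of their level in macrophages. With an estimated correlation 6 of the 10 lists still passed.

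Among the genes that rose, Il7r, the receptor for the survival cytokine interleukin 7, reached 1109 ± 271 CPM in KO_D25 and 355 ± 71.1 in VC_D12 (1.65 ± 0.19, adjusted p = 7.62e-05, chromosome 15, 9505788 to 9530176). Klf2 (1.54 ± 0.29), a factor of T cell recirculation, and Lef1 (1.20 ± 0.34), a factor of naive and memory T cells, rose too, although both fell without passing within the shared cluster (-0.13 and -0.99). Lef1 did not pass without VC_D12 sample 2 or KO_D25 sample 1. Pik3ip1 (2.98 ± 0.38) encodes an inhibitor of PI3 kinase, and Ssbp2 (2.45 ± 0.22) a binder of single-stranded DNA. Cdh1 (2.44 ± 0.33) encodes E-cadherin, a ligand of the integrin CD103, Tgfbr3 (2.32 ± 0.35) a coreceptor for TGF-beta, and Rarg (2.41 ± 0.42) a retinoic acid receptor. The prostaglandin D2 synthase gene Hpgds rose by 2.86 ± 0.37 and passed also within the shared cluster (2.56, adjusted p = 0.0403). St8sia1 (2.23 ± 0.35) encodes a sialyltransferase, and Ftx (2.36 ± 0.31) is a noncoding RNA. As a list the naive and memory genes did not pass (adjusted p = 0.693), with 3 genes higher and Satb1 and Ly6c2 lower. The cytotoxic list did not pass either (adjusted p = 0.15), although 6 of 14 of its genes fell. Interferon-gamma and type I interferon lists had adjusted p = 0.166 and 0.368. Other lists that did not pass were cholesterol synthesis (8 of 14 genes fell, adjusted p = 0.0838) and ribosomal proteins (33 of 89 fell and 3 rose, adjusted p = 0.099).

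Macrophages of KO_D25 tumours had higher transcripts of MHC class II, and lower ones of hypoxia and glycolysis, than those of VC_D12 tumours. The MHC class I list had 4 of 14 genes lower and did not pass (adjusted p = 0.0566). Genes of MHC class II rose along with genes of cDC2 and of microglia, while Arg1, chemokines, glycolysis and S phase genes fell. With an estimated correlation none of these lists passed, with adjusted p = 0.201 for MHC class II and for cDC2, 0.203 for microglia and chemokines, 0.254 for glycolysis and S phase, and 0.33 for hypoxia. The KO_D25 side rested on 71 cells against 2944 in VC_D12. No cluster was named cDC2, and whether cDC2 cells placed in this class account for the rise of MHC class II and cDC2 genes was not tested.

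Of 14455 genes tested, 586 rose and 739 fell, so 44.2% of the changed genes rose. With DESeq2 and its size factors 55.9% rose. The median of all genes lay at -0.14 with edgeR on TMM and at -0.02 with DESeq2. The samples did not overlap for 35.2% of genes, against 10% by chance for samples of equal depth. The KO_D25 samples held 316661 to 846710 UMIs and the VC_D12 samples 30040433 to 49915855. Genes with few counts can separate through this depth alone, so the share cannot be set against 10%. Without VC_D12 sample 1, 2 or 3 the number of changed genes was 210, 222 or 307, with 8386, 8431 or 8464 genes tested. Macrophages came from 5 clusters. Of the 71 KO_D25 cells, 57 lay in 1 cluster that held 816 VC_D12 cells, and a cluster with Il1rn, Thbs1 and Arg1 among its leading genes held 5 and 801. Within the first of these clusters 1352 genes passed, 884 of them also in the whole class.

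The MHC class II list rose with 9 of 10 genes, also 9 adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.201 with an estimated correlation). H2-Ab1, a chain of the class II molecule, rose from 1163 ± 184 to 8779 ± 1116 CPM (2.92 ± 0.17, adjusted p = 1.6e-05). H2-Aa reached 9487 ± 1427 CPM against 1140 ± 247 (3.06 ± 0.20, adjusted p = 1.9e-05, chromosome 17, 34282744 to 34287823), H2-Eb1 rose by 3.21 ± 0.19, and Cd74, the invariant chain, by 2.62 ± 0.17. Ciita, the transactivator of the class II genes, rose by 3.09 ± 0.26, with Dexi on the opposite strand of its locus. The cDC2 markers rose with 4 of 7 genes, 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0151, and adjusted p = 0.201 with an estimated correlation). Among them the lectin gene Mgl2 rose from 5.64 ± 1.10 to 721 ± 440 CPM (7.00 ± 0.54, adjusted p = 0.000323) and the cytokine receptor Flt3 by 4.34 ± 0.28. The other 2 were Cd209a and Clec10a. The mannose receptor Mrc1 rose by 1.97 ± 0.18, but in the different macrophage class of Leiden 2.0 it fell (-0.51, adjusted p = 0.0375). The scavenger receptor Cd163 rose by 7.25 ± 0.74 on 19 UMIs against 9. Hpgd, which inactivates prostaglandins, rose by 5.87 ± 0.34, the leukotriene enzyme Alox5 by 5.02 ± 0.50, the sulfotransferase Sult1a1 by 5.27 ± 0.50 and Rasgrp3, an activator of Ras proteins, by 4.57 ± 0.42. Hpgd and Rasgrp3 are also among the 57 microglia genes used below to gauge microglia RNA. In the catecholamine list, which passed (adjusted p = 0.012, and adjusted p = 0.407 with an estimated correlation), 2 of 10 genes rose, with 4 higher and 1 lower adjusted over the list alone. These were Adrb2, the beta-2 adrenergic receptor (1.55 ± 0.39, adjusted p = 0.034), and Maoa, which degrades monoamines (1.93 ± 0.52, adjusted p = 0.0419, on 10 and 193 UMIs). Adrb2 did not pass without VC_D12 sample 1, 2 or 3 or KO_D25 sample 2 (0.43, adjusted p = 0.542), and Maoa not without KO_D25 sample 1, 2 or 3, the only such fits that tested it.

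Genes of homeostatic microglia rose in macrophages with 9 of 18 members, 12 adjusted over the list alone (adjusted p = 0.0236, and adjusted p = 0.203 with an estimated correlation). The microglia markers, most of which are in that list as well, rose with 6 of 12, 8 adjusted over the list alone (adjusted p = 0.0389, and adjusted p = 0.203 with an estimated correlation). Siglech (5.11 ± 0.45) is a lectin of microglia and plasmacytoid dendritic cells, Gpr34 (3.34 ± 0.38, within Cask on the opposite strand) a lysophospholipid receptor, and Slco2b1 (4.80 ± 0.27) a transporter. Mef2c (2.33 ± 0.26) is a transcription factor of microglia and Tgfbr1 (1.38 ± 0.19) the receptor of their maintenance signal. A set of 57 microglia genes outside the called members of the homeostatic list, Slco2b1 among them, gauged microglia RNA. Over these, KO_D25 macrophages carried a median of 5.83% of the level in KO_D25 microglia beyond that of VC_D12 macrophages, with quartiles of 1.47% and 14.6%. The 57 genes ranged from -5.39% (Syngr1) to 65.8% (Chn2), so no single share of microglia RNA fitted them all. The rise of Mef2c came to 78.8% of its microglia level, that of Tgfbr1 to 44.0%, of Siglech to 12.3% and of Gpr34 to 8.44%.

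Single genes of matrix breakdown and immune suppression fell. No UMI of the collagenase gene Mmp13 was found in KO_D25 macrophages against 9122 in VC_D12, at least 41.0-fold lower (chromosome 9, 7272514 to 7283331). Inhba, a subunit of activin, had 0 and 6623 UMIs, at least 29.8-fold lower (chromosome 13, 16011851 to 16031621). Both bounds use the floor of 3 counts over the group. The membrane metalloproteinase Mmp14 changed by -1.01 ± 0.20, and did not pass without VC_D12 sample 1, 2 or 3. In the matrix and angiogenesis list these 2 metalloproteinases fell and the inhibitor Timp2 rose among 15 genes, with 4 lower and 2 higher adjusted over the list alone (adjusted p = 0.0224, and adjusted p = 0.597 with an estimated correlation). Arg1, which depletes arginine, fell from 562 ± 238 to 13.9 ± 14.5 CPM (-5.02 ± 0.54, adjusted p = 0.00107, chromosome 10, 24915221 to 24927484). The list of immunosuppressive macrophage genes did not pass (adjusted p = 0.884), with Mrc1 and Cd163 higher and Arg1 and Il4ra lower. Without VC_D12 sample 1, 2 or 3 or KO_D25 sample 2 neither Timp2 nor Il4ra passed.

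Chemokine genes fell with 6 of 18 members, also 6 adjusted over the list alone (adjusted p = 0.0222, and adjusted p = 0.203 with an estimated correlation). Ccl7, which attracts monocytes, changed by -2.17 ± 0.48, and did not pass without VC_D12 sample 1 or 2 or KO_D25 sample 2. Ccl8 had 1 UMI against 2399, a ratio of 0.0309 (0.000782 to 0.172), and it did not pass with Leiden 2.0 clusters (-0.60) or without KO_D25 sample 2. Interferon-gamma genes fell with 6 of 18 while Ciita rose, 8 lower and 1 higher adjusted over the list alone (adjusted p = 0.0151, and adjusted p = 0.201 with an estimated correlation). One of them, Iigp1 (-1.57 ± 0.34), encodes a GTPase of intracellular defence, and did not pass without VC_D12 sample 1, 2 or 3. Glycolysis fell with 11 of 15 genes, 13 lower and 1 higher adjusted over the list alone (adjusted p = 0.0222, and adjusted p = 0.254 with an estimated correlation). Pgk1 fell from 754 ± 80.4 to 116.5 ± 58.7 CPM (-2.73 ± 0.30, adjusted p = 0.00073) and Tpi1 changed by -2.28 ± 0.24. Hypoxia genes fell with 6 of 15 while P4ha1 rose, 8 lower and 1 higher adjusted over the list alone (adjusted p = 0.0364, and adjusted p = 0.33 with an estimated correlation). Among them were Bnip3 (-2.74 ± 0.27), which starts mitophagy, and the oxygen sensor Egln3 (-4.86 ± 0.70), which did not pass with Leiden 2.0 clusters (-0.42) or without KO_D25 sample 2.

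Respiratory and replication genes fell as well. Oxidative phosphorylation had 6 of 19 genes lower, 9 adjusted over the list alone (adjusted p = 0.0225, and adjusted p = 0.254 with an estimated correlation), with Cox5a at -1.51 ± 0.21 and Uqcrq at -1.35 ± 0.20. Of the mitochondrial transcripts 6 of 13 fell, 9 adjusted over the list alone (adjusted p = 0.0222, and adjusted p = 0.546 with an estimated correlation), with mt-Co1 at -0.69 ± 0.11, which did not pass without VC_D12 sample 1. S phase genes fell with 14 of 16, 15 adjusted over the list alone (adjusted p = 0.0364, and adjusted p = 0.254 with an estimated correlation). Rrm2 (-3.76 ± 0.51) and Rrm1 (-2.06 ± 0.27) make deoxynucleotides. Clspn, a checkpoint factor of replication, had 2 UMIs against 4365, a ratio of 0.0340 (0.00411 to 0.123). Knl1 of the kinetochore had 3 against 5569 (0.0399, 0.00823 to 0.117). G2 and M phase genes did not pass as a list (adjusted p = 0.0735), although 15 of 19 fell. The chemokine receptor Xcr1, a marker of cDC1, had 3 UMIs against 4468 (0.0498, 0.0103 to 0.146), and did not pass without KO_D25 sample 1 or 2. Complement (3 of 12 fell and Cfh rose, adjusted p = 0.0647), type I interferon (6 of 21 fell, adjusted p = 0.21) and the pro-inflammatory list (5 of 15 fell and 2 rose, adjusted p = 0.0993) did not pass. None of the 13 macrophage lists that passed held with an estimated correlation, and without KO_D25 sample 3 or VC_D12 sample 1 only 1 list passed.

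**Figure D1:**
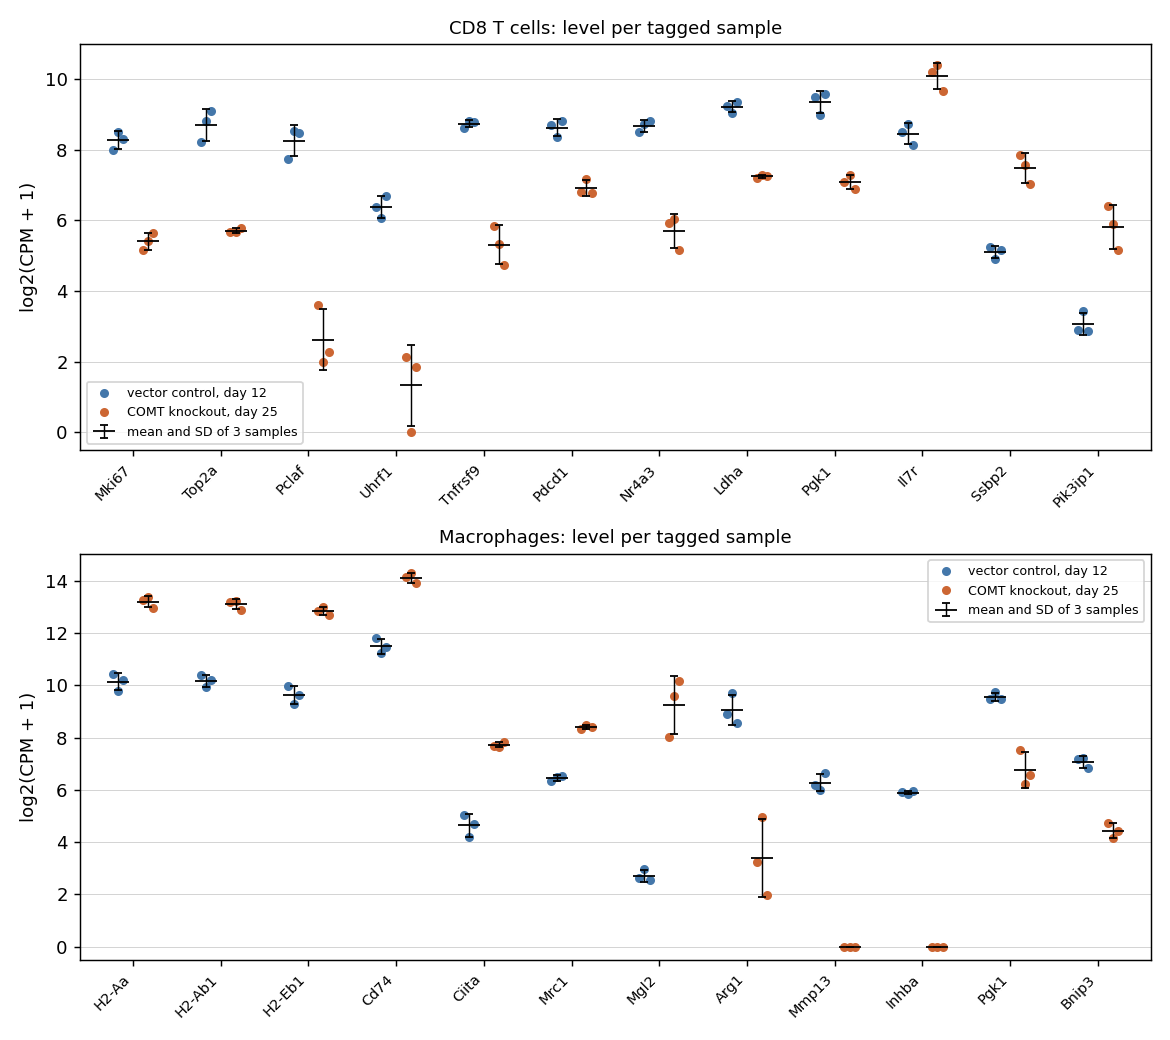
Level of 12 named genes in CD8 T cells and 12 in macrophages of pool 2, as log2(CPM + 1) per sample, with VC_D12 in blue and KO_D25 in orange. In CD8 T cells Mki67 averaged 309.4 CPM in VC_D12 and 41.9 in KO_D25, and in macrophages H2-Aa averaged 1140 and 9487 CPM.

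Few microglia genes passed. Mitochondrial transcripts were lower in KO_D25, and so were the single genes Mndal, Ifi203 and Ifitm1. The lists of type I interferon (0 of 19 genes passed, adjusted p = 0.0735) and interferon-gamma (0 of 16, adjusted p = 0.708) did not pass. Every microglia gene named below lost its call in some fits with 1 sample left out. The list of mitochondrial transcripts had adjusted p = 0.203 with an estimated correlation. VC_D12 microglia were scarce, with 54 cells against 615 in KO_D25.

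Of 10255 genes tested in microglia 4 rose and 13 fell, and 796 had an unadjusted p below 0.05. The count fell to 1 without VC_D12 sample 1 or 2 and to 2 without KO_D25 sample 1 or 2, and rose to 28 without VC_D12 sample 3. The microglia lay in 2 clusters, with 301 KO_D25 and 33 VC_D12 cells in the one and 314 and 21 in the other, which was led by Lpl, Trem2, Gpnmb, Apoe and Spp1. The samples did not overlap for 14.0% of genes, against 10% by chance for samples of equal depth. The VC_D12 samples held 380612 to 457255 UMIs and the KO_D25 samples 3987484 to 6399226, which alone can raise the share. Mitochondrial transcripts fell with 8 of 13, 12 adjusted over the list alone (adjusted p = 0.0222, and adjusted p = 0.203 with an estimated correlation). For mt-Atp6, a subunit of ATP synthase, the level was 9926 ± 1012 CPM in VC_D12 and 4545 ± 331 in KO_D25 (-1.13 ± 0.12, adjusted p = 0.0087). The cytochrome oxidase transcripts mt-Co1 (-0.90 ± 0.12), mt-Co2 (-0.99 ± 0.12) and mt-Co3 (-0.92 ± 0.13) and mt-Nd3 of complex I (-0.92 ± 0.14) fell too. The interferon-inducible genes Mndal (-2.98 ± 0.37) and Ifi203 (-2.80 ± 0.45) overlap each other on the same strand, so their shares of the reads are uncertain. Ifitm1 (-2.87 ± 0.42), an antiviral membrane protein, and Lgals1 (-1.60 ± 0.26), a galectin, also fell. VC_D12 microglia carried a median of 2.76% of the level of 74 macrophage genes in VC_D12 macrophages beyond that of KO_D25 microglia, and the fall of the 5 nuclear genes came to a median of 10.4% of their macrophage level. Monocyte markers passed as a list (adjusted p = 0.0389, and adjusted p = 0.203 with an estimated correlation) with a median of -1.55, while 0 of 5 genes passed singly and 1 adjusted over the list alone. The scavenger receptor gene Colec12 rose from 7.02 ± 8.31 to 124 ± 43.4 CPM (4.26 ± 0.56, adjusted p = 0.0146, chromosome 18, 9707595 to 9882644). Atp5s, a factor coupled to ATP synthase, had 1791 UMIs in KO_D25 and 3 in VC_D12, a ratio of 44.8 (15.3 to 217). Of these UMIs 1360 lay in the 54 positive KO_D25 cells of the first cluster.

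CD4 T cells of KO_D25 tumours had lower transcripts of inhibitory receptors and chemokines than those of VC_D12 tumours. With an estimated correlation neither list passed (adjusted p = 0.201 for each). The single genes Il7r, Tcf7, Bcl2, Fos and Jun were higher and Gzmb was lower. The cell cycle lists did not pass, and whether this differs from CD8 T cells was not tested. At Leiden 2.0 most VC_D12 and most KO_D25 cells lay in different CD4 T clusters.

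Of 6760 genes tested in CD4 T cells 62 rose and 105 fell, among 142 KO_D25 and 113 VC_D12 cells. At Leiden 2.0 the class split into a cluster of 131 KO_D25 and 28 VC_D12 cells and another of 8 and 85. The second had Icos, Ifng and Ccl1 among its leading genes. No fit within 1 of these clusters was made, so a shift between them cannot be told apart from a change within cells. The samples did not overlap for 19.9% of genes, against 10% by chance. The exhaustion list fell with 6 of 13 genes, 8 adjusted over the list alone (adjusted p = 0.0199, and adjusted p = 0.201 with an estimated correlation). Lag3 fell from 222 ± 68.7 to 13.8 ± 8.59 CPM (-3.83 ± 0.41, adjusted p = 0.000383), and Havcr2, the gene of TIM-3, changed by -4.54 ± 0.49, Pdcd1 by -2.87 ± 0.35 and Tigit by -1.59 ± 0.36. Tigit did not pass without VC_D12 sample 1 or 2 or KO_D25 sample 1 or 2. Regulatory T cell markers fell with 3 of 7, 4 adjusted over the list alone (adjusted p = 0.0199, and adjusted p = 0.201 with an estimated correlation). They were Tnfrsf4 (-1.32 ± 0.22), Tnfrsf18 (-1.20 ± 0.23) and Cd4 itself. Tnfrsf18 did not pass without VC_D12 sample 1 or KO_D25 sample 1. Of 5 chemokine genes Ccl3 (-3.39 ± 0.37) and Ccl4 (-2.67 ± 0.31), which attract cells through CCR5, fell, with 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.0361, and adjusted p = 0.201 with an estimated correlation). The granule protease Gzmb changed by -3.42 ± 0.33, while the cytotoxic list did not pass (adjusted p = 0.093). Klri2, a lectin-like receptor gene of NK cells, had 1 UMI against 140, a ratio of 0.00804 (0.000202 to 0.0455). Sema4c, a semaphorin gene, changed by -4.49 ± 0.85 on 4 and 104 UMIs, and did not pass without KO_D25 sample 3. Pgk1 fell (-1.82 ± 0.27) among 6 of 13 glycolysis genes, a list that did not pass (adjusted p = 0.0624). Il7r (1.15 ± 0.19), the memory factor Tcf7 (1.77 ± 0.30) and the survival gene Bcl2 (1.46 ± 0.24) rose, 3 of 10 genes of the naive and memory list (adjusted p = 0.167). Il17rb, the receptor subunit for interleukin 25, had 90 UMIs against 1, a ratio of 101 (17.7 to 4044), with Actr8 on the opposite strand. It is also a leading gene of the cluster named gamma-delta T, with 48 KO_D25 and 3 VC_D12 cells. Whether such cells or their RNA lie among the CD4 T cells was not tested. Trat1, an adaptor of the T cell receptor, rose by 3.69 ± 0.42, the ubiquitin ligase gene Rnf128 by 3.96 ± 0.74 and the cytokine Tnf by 1.59 ± 0.24. Rnf128 did not pass without KO_D25 sample 2, and with doublets kept it was a leading gene of a cluster like the one named gamma-delta T (36 KO_D25 cells and 1 VC_D12 cell). Fos (1.72 ± 0.23) and Jun (1.18 ± 0.25), which respond to stimulation and to tissue dissociation, rose among 5 of 16 genes of the dissociation list (adjusted p = 0.18), and 9 rose adjusted over the list alone. Jun did not pass without VC_D12 sample 1, 2 or 3 or KO_D25 sample 3. Ribosomal proteins (4 of 86 rose, adjusted p = 0.0735) and the S phase (adjusted p = 0.86) and G2 and M phase lists (adjusted p = 0.873) did not pass.

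Macrophages and microglia did not change alike between the groups. The fall of Pgk1, Tpi1, Bnip3, Egln3 and Arg1 was larger in macrophages, and several genes of microglia rose more in macrophages than in microglia themselves. For the MHC class II genes the difference between the classes did not pass.

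In the edgeR interaction, 232 of 11606 genes changed differently, 112 of them toward higher values in macrophages. With limma on the differences per sample 26 genes passed, and only 4 of them were among the 232. Pgk1 differed by -2.77 ± 0.32 (adjusted p = 2.44e-06), with a change of -2.73 in macrophages and -0.05 in microglia. Tpi1 (-2.36 ± 0.31), Bnip3 (-2.62 ± 0.47) and Egln3 (-5.76 ± 0.96) went the same way. Arg1 differed by -3.54 ± 0.60 (adjusted p = 0.000859), with -5.02 in macrophages and -1.76 in microglia. Mmp14 differed by -1.82 ± 0.37 (adjusted p = 0.00461). Slco2b1 (4.96 ± 0.34, adjusted p = 1.73e-10), Hpgd (5.93 ± 0.43), Mef2c (2.60 ± 0.26), Gpr34 (3.38 ± 0.42), Rasgrp3 (4.24 ± 0.41), Alox5 (5.06 ± 0.72) and Tgfbr1 (1.40 ± 0.22) rose more in macrophages. Slco2b1, Hpgd and Rasgrp3 are among the 57 microglia genes that gauge microglia RNA in KO_D25 macrophages. For them such RNA cannot be told apart from a change in macrophages. Mndal fell in microglia (-2.98) and had a change of -0.10 in macrophages (difference 2.73 ± 0.37, adjusted p = 4.79e-05). Atp5s differed by -5.16 ± 0.80 (adjusted p = 0.000245), with a change of 0.47 in macrophages. The differences of H2-Ab1 (2.11 ± 0.63, adjusted p = 0.266), H2-Aa (adjusted p = 0.333), Cd74 (adjusted p = 0.364), H2-Eb1 (adjusted p = 0.375) and mt-Atp6 (0.33, adjusted p = 0.333) did not pass, nor did that of Comt (0.82, adjusted p = 0.231).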

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

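The tests of untagged cells, of cluster resolution, of time since injection, of UMIs per cell, of macrophage RNA in CD8 T cells and of other splits of the samples were chosen only after the results were seen. Every other split puts samples of both groups on each side, so a strong difference between the groups counts as spread and itself keeps the counts low. The size of the gap to the real split is thus no further support for any result below.

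The changes of macrophages and microglia were set apart because they differ between these groups of cells, with 232 genes past the threshold in the test of the difference. In macrophages, but not to the same degree in microglia, Slco2b1, Hpgd, Mef2c and Gpr34 rose, and Pgk1, Tpi1 and Bnip3, genes of glycolysis and hypoxia, fell. Slco2b1 and Hpgd are among the 57 microglia genes used below to gauge microglia RNA in KO_D25 macrophages. For them and for Gpr34, such RNA or misplaced microglia cannot be told apart from a change in macrophages. The count of 232 ran from 139 to 315 with 1 sample left out, and limma on the differences per sample gave 26 genes, only 4 of them among the 232. The other splits of the 6 samples gave at most 3 genes, and 1 of 10 splits, the real one, gave 232, which is too few splits for a share under 0.05.

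Microglia without a sample tag were set apart because they are a signal in cells that no comparison used. Of the kept cells without a tag call 688 were microglia (96.1%), so 50.7% of all 1357 microglia had no tag (exact 95% interval 48.0% to 53.4%). The loss fell mostly on the microglia cluster led by Sparc, P2ry12 and Siglech, where 64.7% had no tag against 18.5% in the one led by Lpl. Of 3024 macrophages 0.298% had no tag, of 539 CD8 T cells 0, which allows up to 0.557%, and of 32 neutrophils 43.8%. No biological explanation of the loss was tested.

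The first pattern weighed is the exchange of macrophages for microglia. Tag loss was excluded as its cause, since microglia would make up only 15.8% of VC_D12 cells if every untagged cell were given to VC_D12, against 35.5% in the lowest KO_D25 sample. Cluster resolution and cell filters were excluded as the whole cause of the microglia difference. It was at least 28.7 percentage points over the clustering and filter alternatives, against 43.2 as reported. The limits for naming clusters were not varied, so naming was not tested. The macrophage fall was smaller at Leiden 2.0 (log2 fold change -1.90 against -3.90) but still passed in edgeR (adjusted p = 0.000309). Genotype and time since injection cannot be told apart, since 0 VC_D12 samples were taken on day 25. Of the 16 classes 13 passed with the real groups and 0 with the other splits, but 1 of 10 splits is too few for a share under 0.05.

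The second pattern is the lower cell cycle programme of KO_D25 CD8 T cells. The lower number of UMIs per cell was excluded as its whole cause, since 22 of 32 genes still fell after thinning, of 23 that could be tested. RNA from macrophages was excluded, since 50 abundant macrophage genes reached a median of 1.94% of their macrophage level in VC_D12 CD8 T cells, at most 13.9%, while the cell cycle genes needed 110%. A shift between CD8 T clusters may account for part of it, since within the cluster shared by both groups Mki67 still fell (-2.29) while Top2a (-1.37, adjusted p = 0.144) did not pass, and whether genotype or day brings it about stays open. For CD8 T cells 1976 genes and 10 lists passed with the real groups, and 0 and 0 with the other splits, where 1 of 10 splits is again too few for a share under 0.05.

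The third pattern is the change of macrophages and microglia, for which RNA exchanged between these cells was weighed. Cells of type cDC2 placed among the macrophages were not weighed, so they stay open as a source of the MHC class II rise. In KO_D25 macrophages 57 microglia genes implied a median of 5.83% microglia RNA (quartiles 1.47% to 14.6%), against 9.63% needed by the 9 homeostatic microglia genes. No single share of microglia RNA fitted the 57 genes, which ranged from -5.39% (Syngr1) to 65.8% (Chn2). The median is thus not a measured level of such RNA. Sparc (0.982%), P2ry12 (6.18%), Sall1 (6.51%), Gpr34 (8.44%), Hexb (9.63%) and Siglech (12.3%), 6 of the 9, lay below the upper quartile but also called for different shares. For them the gauge cannot tell such RNA or misplaced microglia from a change in macrophages. Microglia RNA falls short of Mef2c (78.8%), which lay above the highest of the 57 genes (Chn2, 65.8%). It also falls short of H2-Aa, H2-Ab1, H2-Eb1 and Cd74, which needed 327%, 368%, 471% and 214%. Csf1r (17.3%) and Tgfbr1 (44.0%) lay above the upper quartile, but Hpgd (49.4%) and Abca9 (61.0%) among the 57 genes lay higher. Hpgd itself passed as higher in KO_D25 macrophages, and genes of this kind were not removed from the 57. A rise of such genes in macrophages would make the gauge too high, so it cannot settle Csf1r and Tgfbr1. For the 5 nuclear genes that fell in microglia, macrophage RNA in VC_D12 microglia cannot be told apart from a change in microglia, since the 74 macrophage genes implied 2.76% (quartiles 1.30% to 5.60%) against 10.4% needed. Mitochondrial transcripts were excluded from this explanation, since VC_D12 macrophages held 0.673 of the VC_D12 microglia level as the median of 8 transcripts, at most 0.836.

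Over the other splits of the 6 samples the highest counts were 0 against 1325 real genes in macrophages, 3 against 17 in microglia and 2 against 167 in CD4 T cells. For the lists they were 0 against 13 in macrophages, 0 against 2 in microglia and 0 against 3 in CD4 T cells. In each case 1 of the 10 splits was the only one to give as many, and 10 splits are too few for a share under 0.05. Since the other splits mix the groups, their low counts add nothing to this rank.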

How the results depend on the processing

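The fits with equal cell numbers, with 1 shared cluster and without genes of other classes were chosen only after the results were seen, and so were the fits of genes and lists in macrophages, microglia and CD4 T cells. Over the alternatives, 1633 of 1824 tests of named genes kept their direction and their side of the threshold, 177 were weaker, 1 was stronger and 13 reversed. The reversals were Comt in CD4 T cells (0.19 with doublets kept, 0.0197 with Leiden 2.0, 0.13 thinned, 0.32 with equal cells, 0.000854 with DESeq2, and -0.25 to 0.20 with 1 sample left out), Mrc1 in macrophages (-0.51 with Leiden 2.0), and Bhlhe40 (0.37), Comt (0.16), Klf2 (-0.13) and Lef1 (-0.99) in CD8 T cells of 1 shared cluster. The CD8 T count was 1021 of 6739 genes tested after thinning, and 59 in the shared cluster, which held fewer cells and where folds were also smaller (Top2a -1.37). The macrophage count was 5533 with Leiden 2.0, 92 with 14 cells from each sample, 2896 with DESeq2 and 582 with limma-voom. The Leiden 2.0 class took in a cluster led by Lpl, Gpnmb and Spp1 (207 KO_D25 and 12 VC_D12 cells). Its count and the reversal of Mrc1 thus cover a different mix of cells. Microglia gave 40 with doublets kept, 1 with 13 cells from each sample, 69 with DESeq2 and 188 without the filter on low counts. CD4 T cells gave 74 with 19 cells from each sample and 391 without the filter. With an estimated correlation 6 lists passed in CD8 T cells, 0 in macrophages, 0 in microglia and 0 in CD4 T cells. With the preset correlation 10 passed in microglia and 15 in CD4 T cells. The interaction gave 385 genes without the filter and 26 with limma, 4 of them shared. TMM over classes changed CD4 T (0.38), CD8 T (0.19), neutrophils (1.41), regulatory T cells (-1.63), plasmacytoid dendritic cells (-2.60) and mast cells (-1.09). With doublets kept the class named regulatory T had a share difference of 2.18 percentage points and an abundance change of 1.93, because a cluster led by Gata3, Il1rl1 and Il17rb (36 KO_D25 cells and 1 VC_D12 cell), like the one otherwise named gamma-delta T, took that name. The cluster with all 8 regulatory T markers still held 9 and 30 cells, and no gamma-delta T class was left. Under the strict cell filter mast cells had -0.0383 percentage points and -0.0139. NK cells had -0.75 with Leiden 2.0. Tumour or mesenchymal cells had -4.24 under the strict filter. Apart from these renamed clusters, the cause was not tested.

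With 1 sample left out in turn, the pool 1 difference ranged from 9.0 (without VC_D12 sample 4) to 66.0 cells (without VC_D12 sample 3), and regulatory T cells ranged from -0.422 to 0.120 percentage points and from -0.69 to 0.34 in abundance, positive without VC_D12 sample 2. Mast cells ranged from -0.0958 to 0.115, negative without VC_D12 sample 1 or 3 or KO_D25 sample 2 or 3, and from -0.51 to 1.39 in abundance, negative without VC_D12 sample 3 or KO_D25 sample 2. NK cells (-2.59 to -1.38) did not pass without VC_D12 sample 1 or 2 or KO_D25 sample 1 or 3, cDC1 (-2.42 to -1.29) without VC_D12 sample 2 or KO_D25 sample 2, and tumour or mesenchymal cells (-2.05 to -1.32) without KO_D25 sample 3. Macrophage genes ranged from 210 to 1895 (210, 222 and 307 without VC_D12 sample 1, 2 and 3, and 707 without KO_D25 sample 2). Microglia genes ranged from 1 to 28 (1 without VC_D12 sample 1 or 2, 28 without sample 3, 2 without KO_D25 sample 1 or 2), CD8 T genes from 1411 to 1715, and CD4 T genes from 95 to 195 (111, 99 and 95 without KO_D25 sample 1, 2 and 3). Macrophage lists ranged from 1 to 13 (1 without VC_D12 sample 1 or KO_D25 sample 3, 5 without VC_D12 sample 2), microglia lists from 0 to 6 (0 without VC_D12 sample 1 or any KO_D25 sample, 5 and 6 without VC_D12 sample 2 and 3), CD8 T lists from 9 to 11 (the disease-associated microglia list did not pass without KO_D25 sample 1, 2 or 3), and CD4 T lists from 0 to 5 (0 without VC_D12 sample 1 or KO_D25 sample 1 or 3, 5 without VC_D12 sample 3). The interaction ranged from 139 (without KO_D25 sample 2) to 315. Leiden 0.5 gave no CD4 T, regulatory T, gamma-delta T, cDC1 or plasmacytoid dendritic class and no unnamed cluster of the same kind, and the strict filter left too few microglia for a fit. No paired analysis was possible because the labels give no pairing between the groups. Depth limits the fits, with 316661 to 846710 UMIs per KO_D25 sample in macrophages, 380612 to 457255 per VC_D12 sample in microglia and 328249 to 883610 per sample in CD4 T cells.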

Other observations

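The cells with a UMI of single genes were counted only after the values of these genes were seen. CD8 and CD4 T cells of KO_D25 tumours changed in part in the same genes. Of 6711 genes tested in both, 34 rose in both, where independent lists would share 6.66, and 67 fell in both, where they would share 13.8. No gene moved in opposite directions past both thresholds, a count of 0. Il7r, Pik3ip1, Ssbp2 and Trat1 were among the shared rises, and Lag3, Pdcd1, Tnfrsf9, Hif1a, Ldha and Pgk1 among the shared falls. Both classes came from the same 6 samples, so the sharing is not independent evidence.

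Among lymphocytes, UMIs of Slc17a6, which encodes the vesicular glutamate transporter VGLUT2 of neurons, were found mostly in VC_D12 CD8 T cells of the cluster with Gzmb among its leading genes. In CD8 T cells it had 1 UMI in KO_D25 and 249 in VC_D12, a ratio of 0.00574 (95% interval 0.000145 to 0.0323, chromosome 7, 51622006 to 51671119). In that cluster 30 of 189 VC_D12 cells had a UMI (15.9%, median depth 15769 UMIs), and in the other CD8 T cluster 0 of 67 (median 10445). Only 11 KO_D25 cells lay in the first of these clusters. Of them 0 had a UMI, which allows up to 27.3%, and in the other cluster 1 of 272 KO_D25 cells had one. The ratio thus does not show a difference between the groups within a cluster. Of VC_D12 CD4 T cells 5 of 113 had one (4.42%), and of VC_D12 NK cells 0 of 89 (median 17250). The counts of 0 of 67 and 0 of 89 allow up to 4.48% and 3.37% of cells with a UMI at these depths. All such limits are on cells with a UMI, not on cells expressing the gene. In VC_D12 macrophages, with medians of 24913 to 39043 UMIs, 4 clusters had it in 0.499% to 0.957% of cells and the other in 0 of 425. Klri2, a receptor gene of NK cells, was found in 23 of 113 VC_D12 CD4 T cells (20.4%), in 1 of 142 KO_D25 CD4 T cells (0.704%) and in 59 of 89 VC_D12 NK cells (66.3%, median 17250). Among KO_D25 NK cells 9 of 10 had it (90%). In the CD8 T cluster with Gzmb 33 of 189 VC_D12 (17.5%) and 2 of 11 KO_D25 cells (18.2%) had it. Outside CD4 T cells Klri2 was thus not rarer in these few KO_D25 cells. The VC_D12 CD4 T cells had a median of 13974 UMIs, and the VC_D12 macrophage clusters, with their higher depth, had Klri2 in 0 to 1.12% of cells.

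Atp5s and Colec12, 2 of the 4 genes that rose in KO_D25 microglia, were spread differently over the microglia clusters. Atp5s was found in 17.9% of KO_D25 cells of the first cluster and in 18.8% of the other, which was led by Lpl, in 0 of 33 VC_D12 cells of the first (up to 9.09% of cells with a UMI, which does not limit cells expressing the gene) and 3 of 21 of the other (14.3%), and in 10.1% to 19.8% of VC_D12 macrophages per cluster. The 54 positive KO_D25 cells of the first cluster held 1360 UMIs, and the 59 of the other held 431. Colec12 was found in 156 of 314 KO_D25 cells of the cluster led by Lpl (49.7%), in 4 of 21 VC_D12 cells of that cluster (19.0%), and in 2 of 301 KO_D25 cells of the other (0.664%).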
